A study of Homo sapiens with 26 samples.

How the data were processed

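The series measured chromatin immunoprecipitation followed by sequencing in HEK293 cells, a human embryonic kidney line with a stable 5xUAS-luciferase reporter in an intron of NCOA5. Cells were transfected with DAXX-Myc alone, with DAXX-Myc and GAL4DBD-CBX2.1, or with DAXX-Myc and GAL4DBD-CBX2.2. From each, chromatin was recovered with an antibody to the GAL4 DNA-binding domain or to the Myc tag, or kept as input without antibody, per the labels. Chromatin was crosslinked with formaldehyde, and libraries were made with the NEB Ultra II kit, per the labels' protocols.

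The deposited tables hold raw read counts per transcription start site (TSS) window of 2000 bp, as whole numbers without normalization, for Entrez gene identifiers. The builds GRCh37 and hg19 are named in the submitters' processing notes. The aligner and the counting program are not given in the sources used here. Each table has 22192 TSS windows, of which 92 have no gene symbol in a RefSeq table of assembly GRCh38.p14, used for names alone. No coordinates were taken from it. DAXX has no window in the tables and was not analysed here. The counts of 310 windows equalled those of another window in every library, so genes that share a window cannot be separated, and 3 windows had 0 counts in every library.

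Libraries were grouped by transfection and antibody into 9 groups. Counts of the cells with DAXX alone and with CBX2.1 were fitted together, those of CBX2.2 cells on their own, and all 26 libraries jointly for comparisons across the tables. TMM factors, the filterByExpr filter with a minimum count of 10, and quasi-likelihood F tests were computed in edgeR 4.0.16 under R 4.3.3, with 1 coefficient per group and no replicate term. P-values were adjusted over all TSSs tested by the Benjamini-Hochberg method, and a TSS was called at an adjusted p of 0.05. The filter left 22141 TSSs in the first table, 22140 in the second and 22148 jointly. Standard errors of log2 changes were taken from the F statistic. Counts scaled to 1e6 reads per library (CPM) used the TMM factors, with a prior count of 2 on the log2 scale. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.

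Comparisons were each antibody in CBX2.1 against DAXX-only cells, input likewise, each antibody against input within each kind of cell, and differences of the signals over input between kinds of cell. CBX2.2 libraries come from another table, so each test of antibody signal across tables was made over the input of the same cells. Genes named are, per comparison, up to 10 called TSSs with the largest change in each direction among those with a mean count of at least 20 in 1 group and no overlap between the libraries of the groups. Where no TSS was called, those with the smallest p are given. Also to be named were NCOA5, CBX2 and ATRX, and in each list the 4 members with the highest mean count over all libraries. The compared libraries are among these, so the rule favours members that gained signal. Such members need not stand for their list. Apart from a few genes left out of the text, these members are given for GAL4 and Myc of CBX2.1 against DAXX-only cells and for Myc against input in DAXX-only cells. In the other comparisons, and among the TSSs with the largest change, the text gives examples picked after their values were seen.

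Gene lists were HOX genes, developmental transcription factors, WNT, BMP and hedgehog ligands, Polycomb subunits, H3.3 chaperones and PML bodies, replication-dependent histone genes, ribosomal protein genes, numbered ZNF genes, imprinted genes, olfactory receptor genes, canonical MYC targets, interferon-stimulated genes, germline genes, and heat shock and stress genes. Each was tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. The 126 list tests were adjusted as 1 family. Gene lists, the rule for named genes and the alternative settings were fixed before the data were examined.

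Alternatives were the size factors of DESeq2, no filter on low counts, the Wald test of DESeq2 1.42.0, scaling to the summed counts of olfactory receptor TSSs, only the compared groups in the fit, a replicate block, differences over input, only TSSs above the median count, and leaving out each library in turn. Total counts per library ran from 691085 to 1641541. The median count per TSS was 30 to 54, at which counting error alone gives a coefficient of variation of 18.3% to 13.6%.

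The tests were run on simulated counts with known changes. Fewer TSSs were changed there than were called in the data, with as many raised as lowered. Error and recovery where many more TSSs gain than fall were not simulated. For the GAL4 comparison of CBX2.1 with DAXX-only cells, changes of 1.5, 2 and 4 times were recovered in 1.49%, 26.9% and 97% of TSSs, with 4 false calls among 87. For the Myc comparison the shares were 2.99%, 35.8% and 98.5%, with 5 false calls among 96. For GAL4 against input in CBX2.2 cells they were 2.99%, 23.9% and 86.4%, with 2 among 77. For the difference in Myc signal over input between CBX2.2 and CBX2.1 cells they were 1.49%, 4.48% and 66.7%, with 2 among 50. Figures were drawn with matplotlib 3.10.9. GC content was not examined, as no genome of this build was at hand.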

Results

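Chromatin immunoprecipitation and sequencing were carried out in HEK293 cells to examine where DAXX and the CBX2 isoforms CBX2.1 and CBX2.2 sit on the genome. DAXX is a chaperone of the histone variant H3.3, and CBX2 is a subunit of Polycomb repressive complex 1, which keeps developmental genes silent. Cells expressed Myc-tagged DAXX alone (DAXX-only cells), or together with CBX2.1 (CBX2.1 cells) or CBX2.2 (CBX2.2 cells) fused to the GAL4 DNA-binding domain. Each was profiled with a GAL4 antibody, a Myc antibody and no antibody (input), with 3 libraries per group and 2 for the input of CBX2.2 cells. Values are read counts in 2000 bp windows at transcription start sites (TSSs).

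Total counts of DAXX-only cells were 726906, 773315 and 842674 for GAL4, 1008858, 1069225 and 872489 for Myc, and 691085, 915416 and 771705 for input. Those of CBX2.1 cells were 1126066, 1480401 and 1374021 for GAL4, 1489369, 1337271 and 1641541 for Myc, and 707748, 742878 and 736295 for input. Those of CBX2.2 cells were 1055319, 1059151 and 953530 for GAL4, 1173809, 1401272 and 1083816 for Myc, and 763953 and 782402 for input. Replicates correlated across TSSs with r = 0.462 to 0.537 in the GAL4 libraries of DAXX-only cells, 0.54 to 0.549 in their inputs and 0.88 to 0.899 in the Myc libraries of CBX2.1 cells. Replicates of each group differed by more than counting error, with a chi-square per degree of freedom of 1.99 to 5.53.

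The GAL4 comparison of CBX2.1 with DAXX-only cells, which hold no GAL4 fusion, asked which TSSs carried GAL4DBD-CBX2.1. GAL4 signal was higher in CBX2.1 cells at BMP2 (Entrez ID 650), a bone morphogenetic protein, with 469 ± 90.4 CPM against 40.4 ± 5.55 CPM (SD, n = 3 each). This was a log2 change of 3.53 ± 0.25 (SE, edgeR adjusted p = 5.01e-22). A larger change was at B3GAT1 (ID 27087), a glucuronyltransferase that makes the HNK-1 epitope, with 193 ± 29.5 against 15.6 ± 7.84 CPM and a log2 change of 3.64 ± 0.30 (adjusted p = 2.03e-18). Also higher were the secretory kinase gene FAM20C at 3.60, RIMS2 at 3.55, the cadherin gene CDH4 at 3.52, the acid-sensing channel gene ASIC2 at 3.51, and the glutamate transporter gene SLC1A2 and potassium channel gene KCNK12, both at 3.48. GAL4 signal was lower at the heat shock cognate gene HSPA8 (ID 3312), with 9.16 ± 3.24 against 41.9 ± 11.1 CPM and a log2 change of −2.15 ± 0.38 (adjusted p = 1.31e-06). The chemokine gene CCL22 changed by −2.19 ± 0.43 (adjusted p = 9.85e-06), ZNF569 by −2 and FBXO11 by −1.96. At each of these genes all 3 libraries of CBX2.1 cells lay beyond all 3 of DAXX-only cells, as the rule for naming required.

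edgeR quasi-likelihood called 9391 of 22141 TSSs, 6020 higher with a median log2 change of 1.46 and 3371 lower with a median of −1.01. Scaled to olfactory receptor TSSs, 5010 were higher and 4912 lower, and the median of all TSSs moved from −0.10 to −0.29. As a difference of the signals over input, 5853 TSSs were called, 4590 higher and 1263 lower.

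Secreted developmental signals had the largest median GAL4 change among the gene lists, which were not tested against each other. Of 35 WNT, BMP and hedgehog ligands, GAL4 signal was higher at 24 and lower at 1, or 24 and 2 adjusted over the list alone, with a median log2 change of 1.86 and library medians of 1.69, 2.37 and 1.47. Besides BMP2, the list held BMP6 at 3.24 ± 0.25 (adjusted p = 5.19e-20), WNT9A at 2.86 ± 0.25 (adjusted p = 7.89e-18) and SHH, the sonic hedgehog gene, at 2.72 ± 0.24 (adjusted p = 4.99e-17). camera gave an adjusted p of 6.67e-11 for this list, and 0.0324 with an estimated correlation. Developmental transcription factors were higher at 97 and lower at 6 of 134 TSSs, or 101 and 7 adjusted over the list alone, with a median of 1.48. Among them were the homeobox genes GBX1 at 2.90, IRX4 at 2.47 and LHX3 at 2.03, and the zinc finger gene ZIC2 at 2.59. camera gave an adjusted p of 2.89e-16 (adjusted p = 0.101 with an estimated correlation). Of 39 HOX genes 15 were higher and 3 lower, or 15 and 4 adjusted over the list alone, with a median of 0.37. Among the higher ones were HOXB7 at 2.29, HOXB9 at 1.90 and HOXC9 at 1.87. The list as a whole was not called by camera (adjusted p = 0.166) but was by fry (adjusted p = 9.5e-05). Of 126 list tests over all comparisons camera called 50 with the preset correlation and 3 with an estimated one, each time the WNT, BMP and hedgehog ligands.

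Of 28 Polycomb subunit genes 18 were higher and 2 lower, the same numbers as adjusted over the list alone, with a median of 1.26. They included the polyhomeotic gene PHC2 at 2.32, PCGF5 at 2.07 and PCGF6 at 1.71. camera gave an adjusted p of 0.00172 (adjusted p = 0.18 with an estimated correlation). Ribosomal protein genes lay lower, with 3 higher and 17 lower of 78, or 3 and 13 adjusted over the list alone, and a median of −0.37 (adjusted p = 0.00078, and adjusted p = 0.274 with an estimated correlation). RPL7A at −0.20 (adjusted p = 0.479) and RPS19 at −0.30 (adjusted p = 0.377) were not called. Germline genes had 4 higher and 12 lower of 40, the same numbers as adjusted over the list alone, and a median of −0.65 (adjusted p = 0.00626, and adjusted p = 0.161 with an estimated correlation). Among the germline members that rose were MAEL at 2.14, CYP26B1 at 1.82 and PIWIL4 at 1.43. Replication-dependent histone genes had 1 higher and 12 lower of 62, or 0 and 6 adjusted over the list alone, and a median of −0.38 (adjusted p = 0.0214, and adjusted p = 0.26 with an estimated correlation).

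The other lists were not called by camera in this comparison. fry, which tests whether a list moves 1 way on balance without setting it against other genes, called 67 of the 126 list tests. Of the lists below it called heat shock and stress genes (adjusted p = 9.5e-05), imprinted genes (adjusted p = 0.000258), H3.3 chaperones and PML bodies (adjusted p = 0.00292) and canonical MYC targets (adjusted p = 0.0123) as higher. H3.3 chaperones and PML bodies had 7 higher and 4 lower of 23, or 7 and 4 adjusted over the list alone (adjusted p = 0.435), with H3-3A, which encodes H3.3 itself, at 1.84 and the chaperone genes ASF1A at 1.92 and UBN1 at 1.46. Heat shock and stress genes had 14 higher and 2 lower of 29, or 15 and 4 adjusted over the list alone (adjusted p = 0.0833), with EGR2 at 2.35 and JUNB at 1.80. Imprinted genes had 17 higher and 4 lower of 41, or 17 and 6 adjusted over the list alone (adjusted p = 0.307), with IGF2 at 3.12 and PHLDA2 at 2.14, a mean of 0.37 and a median of −0.0020. Canonical MYC targets had 12 higher and 3 lower of 47, or 12 and 1 adjusted over the list alone (adjusted p = 0.936), with UBTF at 2.53 and ODC1 at 1.90. Interferon-stimulated genes had 5 higher and 4 lower of 35, or 5 and 4 adjusted over the list alone (adjusted p = 0.157). Their median was −0.59, with IRF1 at 2.68 among the 5 that rose. Numbered ZNF genes had 84 higher and 85 lower of 507, or 81 and 73 adjusted over the list alone (adjusted p = 0.0742). Olfactory receptor genes had 45 higher and 13 lower of 329, or 21 and 8 adjusted over the list alone (adjusted p = 0.775), and their median of 0.21 was opposite in sign to the test. Scaled to olfactory receptor TSSs, the medians of the H3.3 list moved from 0.17 to −6.1e-05 and of the MYC targets from 0.065 to −0.15.

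Further list members with high counts went both ways for GAL4. HOXC13 at 1.52, ZNF746 at 2.16, ZNF777 at 2.04, CDKN1C at 2.12, KCNQ1OT1 at 1.19, SRM at 1.34, IFIT5 at 1.71, HERC5 at 1.56 and KLF4 at 1.39 were called higher. Calls lost under other settings were those of NOP56 at 0.78, RPS2 at 0.67, H2AC11 at 0.67 and OR8J3 at 0.94, and, without GAL4 replicate 2 of CBX2.1 cells, of the lower SYCP2 at −0.82 and IRF7 at −0.76. ZNF595 and ZNF718, which share a window, at 0.40, the histone genes H2AC25 at 0.56, H2BC26 at 0.62 and H1-4 at 0.58, the olfactory receptor genes OR5M9 at 0.32, OR4B1 at 0.21 and OR9I1 at 0.49, and DUSP1 at 0.55 were not called.

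The Myc comparison of CBX2.1 with DAXX-only cells asked whether DAXX-Myc signal differed in the presence of CBX2.1. Myc signal was higher in CBX2.1 cells at BMP2, with 240 ± 19.7 against 46.3 ± 8.91 CPM and a log2 change of 2.38 ± 0.23 (adjusted p = 4.33e-13). Myc signal was also higher at PGBD5 (ID 79605), a domesticated transposase gene, with 202 ± 13 against 37.6 ± 5.5 CPM and a log2 change of 2.42 ± 0.25 (adjusted p = 6.21e-12). ARHGEF7 at 2.39, ST6GAL2 at 2.34, the synaptic scaffold gene SHANK3 at 2.32, the vesicular acetylcholine transporter gene SLC18A3 and the channel gene HCN2, both at 2.30, and SALL3 at 2.25 were higher too. Losses were smaller and fewer, among them GARIN4 at −1.5 ± 0.37 (adjusted p = 0.00109), CMPK2 at −1.43 and the small nucleolar RNA gene SNORA30 at −1.40. At each of these genes the libraries of the groups did not overlap, as the rule for naming required. edgeR quasi-likelihood called 4300 of 22141 TSSs, 3922 higher with a median of 1.11 and 378 lower. As a difference of the signals over input, 2152 were called, 2063 higher and 89 lower.

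The 3 lists that camera called higher for GAL4 signal it also called higher for Myc signal. WNT, BMP and hedgehog ligands were higher at 20 and lower at 1 of 35 TSSs, or 22 and 1 adjusted over the list alone, with a median of 1.15 and library medians of 1.11, 1.10 and 1.19 (adjusted p = 1.89e-10, and adjusted p = 0.0281 with an estimated correlation). WNT9A rose by 2.05 ± 0.23 (adjusted p = 4.86e-11), BMP6 by 1.85 ± 0.24 (adjusted p = 1.3e-09) and SHH by 1.79 ± 0.23 (adjusted p = 2.49e-09). Developmental transcription factors were higher at 79 and lower at 0 of 134, or 83 and 0 adjusted over the list alone, with GBX1 at 1.82, IRX4 at 1.62 and LHX3 at 1.61 (adjusted p = 1.73e-13, and adjusted p = 0.101 with an estimated correlation). Polycomb subunit genes were higher at 13 of 28, or 15 adjusted over the list alone, with PHC2 at 1.46 (adjusted p = 0.00308, and adjusted p = 0.176 with an estimated correlation). Heat shock and stress genes were higher at 11 of 29, or 12 adjusted over the list alone, with EGR2 at 1.31 and JUNB at 1.28 (adjusted p = 0.0102, and adjusted p = 0.18 with an estimated correlation). HOX genes were higher at 10 of 39, also adjusted over the list alone (adjusted p = 0.083), and H3.3 chaperones and PML bodies at 6 of 23, also adjusted over the list alone (adjusted p = 0.247), with UBN1 at 1.75 and H3-3A at 1.5. Ribosomal protein genes had a median of −0.23 with 1 of 78 TSSs lower and 0 adjusted over the list alone (adjusted p = 0.00121, and adjusted p = 0.284 with an estimated correlation), and RPS19 stood at 0.15 (adjusted p = 0.719). Replication-dependent histone genes had a median of −0.20 with 1 of 62 lower and 0 adjusted over the list alone (adjusted p = 0.00235, and adjusted p = 0.164 with an estimated correlation). Interferon-stimulated genes had a median of −0.26 with 2 higher and 2 lower of 35, or 1 and 2 adjusted over the list alone (adjusted p = 0.0365, and adjusted p = 0.161 with an estimated correlation).

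Further list members with high counts for Myc in CBX2.1 against DAXX-only cells were HOXC9 at 1.67, HOXB9 at 1.44, HOXB7 at 1.23, ZIC2 at 1.45, ZNF746 at 1.59, ZNF777 at 1.16, PHLDA2 at 1.52, CDKN1C at 1.01, IGF2 at 1.92, UBTF at 1.80, SRM at 1.09, IRF1 at 1.66, MAEL at 1.08 and PIWIL4 at 0.92, all called higher. HOXC13 at 1.29, PCGF5 at 1.19, ASF1A at 1.04, ODC1 at 1.34 and CYP26B1 at 1.05 were called, but not as a difference over input, and the calls of IFIT5 at 0.69 and KLF4 at 0.67 were lost under several settings. PCGF6 at 0.59, NOP56 at −0.046, IRF7 at −0.39, HERC5 at 0.28, SYCP2 at −0.36, KCNQ1OT1 at 0.56, DUSP1 at 0.50, ZNF595 and ZNF718 at 0.23 and RPL7A at 0.079 were not called. Nor were RPS2 at 0.0071, H2AC25 at −0.11, H2BC26 at −0.080, H1-4 at 0.33, H2AC11 at 0.13, OR8J3 at 0.67, OR5M9 at 0.16, OR4B1 at −0.020 and OR9I1 at −0.065. fry also called HOX genes (adjusted p = 0.000525), H3.3 chaperones and PML bodies (adjusted p = 0.00526) and imprinted genes (adjusted p = 0.0099) as higher, and did not call ribosomal protein genes (adjusted p = 0.0934).

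**Figure D1:**
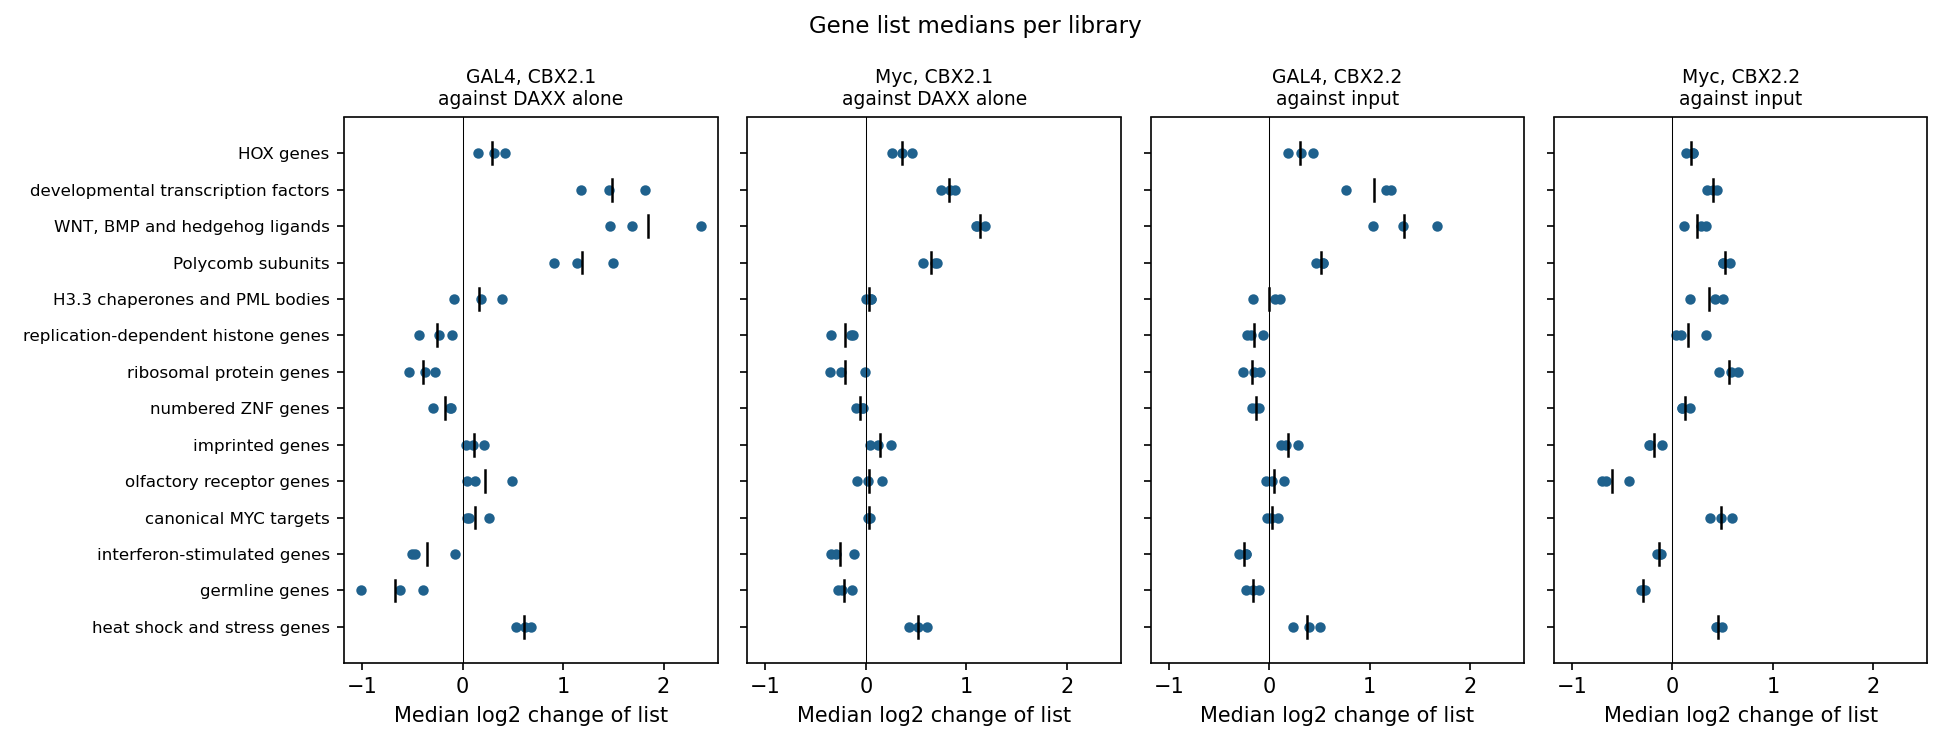
Median log2 change of each gene list (horizontal axis) for single libraries (points) and their mean (bar), for GAL4 and Myc signal of CBX2.1 cells against the mean of DAXX-only cells and of CBX2.2 cells against the mean of their input. WNT, BMP and hedgehog ligands sat at 1.47 to 2.37 for GAL4 and 1.10 to 1.19 for Myc in CBX2.1 cells, and at 1.03 to 1.67 for GAL4 and 0.12 to 0.33 for Myc in CBX2.2 cells.

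Most TSSs that gained Myc signal also gained GAL4 signal, while many that gained GAL4 signal were not called for Myc. Of the 3922 TSSs with more Myc signal in CBX2.1 cells, 3790 (96.6%) also had more GAL4 signal, against 1070 for independent calls. These were 63% of the 6020 TSSs with more GAL4 signal, and 0 TSSs had more GAL4 and less Myc signal, against 103. Ranked by GAL4 change into 10 groups of like size, the top group had a median GAL4 change of 2.13 and a Myc change of 1.30 (1.23 to 1.34 in single libraries), and 94.8% of its TSSs were called higher for Myc. In the bottom group the GAL4 change was −1.11 and the Myc change −0.35. The input change of the top group was −0.031. Across TSSs, which are not independent replicates, GAL4 and Myc changes correlated with Pearson r = 0.832 and Spearman rho = 0.745. The libraries behind both changes are separate.

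**Figure D2:**
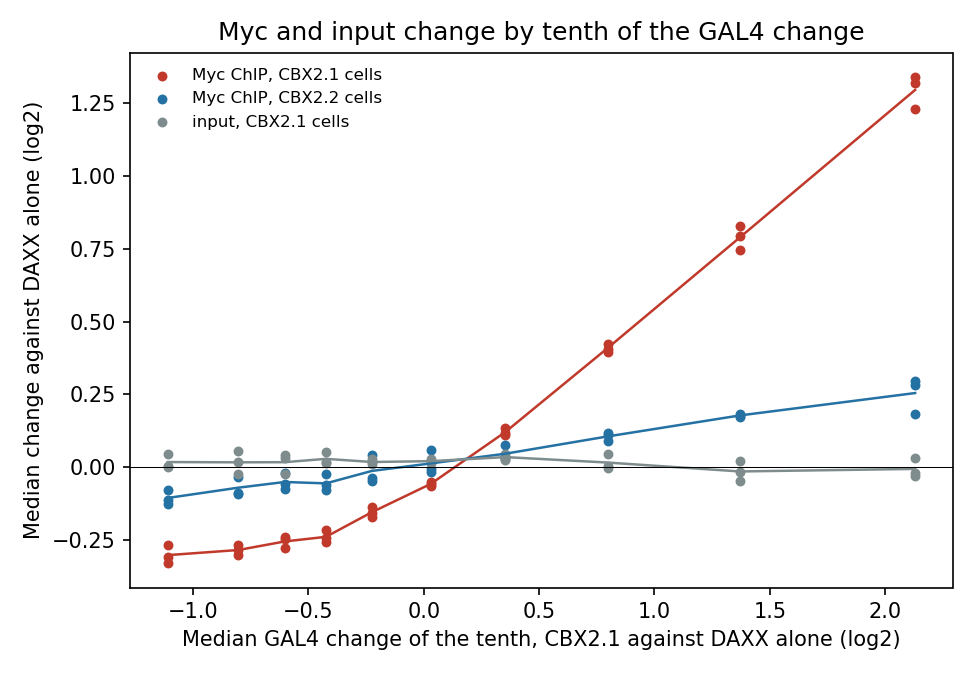
Median change in Myc or input signal against the same signal of DAXX-only cells, without correction for input (vertical axis, log2), in 10 groups of TSSs ranked by their GAL4 change in CBX2.1 cells (horizontal axis, median log2 change of the group). Points are single libraries and lines their means. In the top group the Myc libraries of CBX2.1 cells lay at 1.23 to 1.34 and those of CBX2.2 cells at 0.18 to 0.30.

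Input of CBX2.1 against DAXX-only cells gave the background of these comparisons. BMP2 stood at −0.14 ± 0.28, and among the smallest p-values were those of DUSP6 at 1.18 ± 0.31, MAPK9 at 1.07 ± 0.30 and BARD1 at −1.38 ± 0.40 (adjusted p = 1 for each). edgeR called 0 of 22141 TSSs, with 749 at an unadjusted p under 0.05, and DESeq2 called 0, with 681. Canonical MYC targets had a median of −0.15 with 0 of 47 TSSs called, also adjusted over the list alone (adjusted p = 0.033, and adjusted p = 0.246 with an estimated correlation).

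Myc signal over input in DAXX-only cells asked where DAXX-Myc sat without a CBX2 fusion. It was higher than input at DENR (ID 8562), a translation reinitiation factor, with 321 ± 38.2 against 38.9 ± 15.1 CPM and a log2 change of 3.07 ± 0.28 (adjusted p = 1.24e-14). The transcriptional kinase gene CDK12 stood at 2.95 ± 0.28 (adjusted p = 6.76e-14), RNF167 at 2.59, the mitochondrial carrier gene SLC25A11 at 2.49 and ERCC6L2 at 2.42. Ribosomal protein genes were higher at 18 of 78 TSSs, or 28 adjusted over the list alone, with a median of 0.45 and library medians of 0.61, 0.52 and 0.37. RPS19 rose by 1.93 ± 0.26 (adjusted p = 4.24e-08). camera gave an adjusted p of 9.69e-14 (adjusted p = 0.0942 with an estimated correlation). Canonical MYC targets were higher at 5 of 47, or 7 adjusted over the list alone, with UBTF at 1.46 and NOP56 at 0.96, while ODC1 at 0.68 (adjusted p = 0.128) and SRM at 0.22 (adjusted p = 0.685) were not called (list adjusted p = 7.13e-05, and adjusted p = 0.0942 with an estimated correlation). H3.3 chaperones and PML bodies were higher at 4 of 23, or 6 adjusted over the list alone (adjusted p = 0.00626, and adjusted p = 0.161 with an estimated correlation). Polycomb subunit genes were higher at 5 of 28, also adjusted over the list alone, with a median of 0.35 (adjusted p = 0.00172, and adjusted p = 0.161 with an estimated correlation). Developmental transcription factors were higher at 6 of 134, or 5 adjusted over the list alone, with a median of 0.18 (adjusted p = 0.00626, and adjusted p = 0.389 with an estimated correlation). Of all 22141 TSSs 871 were higher, a share near that of this list. Heat shock and stress genes were higher at 4 of 29, or 5 adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.26 with an estimated correlation). Among developmental genes ZIC2 stood at 1.49, BMP2 at 0.26 (adjusted p = 0.626) and IRX4 at 0.19 (adjusted p = 0.708). Olfactory receptor genes had a median of −0.38, with 0 higher and 4 lower of 329, or 0 adjusted over the list alone (adjusted p = 2.47e-11, and adjusted p = 0.161 with an estimated correlation). The chemokine gene CCL19 at −1.77 and the synaptonemal complex gene SYCP1 at −1.52 were lower.

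Further list members with high counts for Myc over input in DAXX-only cells were mostly not called. RPS2 at 0.95, RPL7A at 0.87, PCGF5 at 1.04, H3-3A at 1.02, ASF1A at 0.94, H2BC26 at 0.95, H2AC25 at 0.86 and DUSP1 at 1.18 were called higher, and each call was lost without 1 or more of the single libraries. HOXB9 at 0.47, HOXC9 at 0.21, HOXC13 at 0.50, HOXB7 at 0.39, LHX3 at 0.16, GBX1 at 0.59, WNT9A at 0.59, SHH at 0.30, BMP6 at 0.25, PHC2 at 0.53, PCGF6 at 0.34 and UBN1 at 0.0044 were not called. Nor were H1-4 at 0.67, H2AC11 at 0.66, ZNF595 and ZNF718 at 0.019, ZNF746 at 0.51, ZNF777 at 0.66, PHLDA2 at 0.68, CDKN1C at 0.57, IGF2 at 0.32, KCNQ1OT1 at 0.59, OR8J3 at −0.81, OR5M9 at −0.41, OR4B1 at −0.57 and OR9I1 at −0.049. IRF1 at 0.34, IFIT5 at 0.50, HERC5 at 0.85, IRF7 at 0.63, PIWIL4 at 0.26, CYP26B1 at 0.46, MAEL at −0.080, SYCP2 at −0.11, JUNB at 0.54, EGR2 at 0.16 and KLF4 at −0.079 were not called either. fry did not call developmental transcription factors (adjusted p = 0.07).

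edgeR quasi-likelihood called 1027 TSSs, 871 higher and 156 lower. Scaled to olfactory receptor TSSs, 4106 were higher and 11 lower, and the median of all TSSs moved from −0.026 to 0.36, so the lower calls depend on the scaling. Olfactory receptor genes, its reference, themselves had a median of −0.38, so this loss of lower calls follows from the choice of reference. The count was 578, 609 and 501 without input replicate 1, 2 and 3, and 478 and 407 without Myc replicate 1 and 2. Myc chromatin of cells without DAXX-Myc was not analysed here, so antibody background, such as binding of untagged MYC, is not separated from DAXX-Myc in this comparison.

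In CBX2.1 cells Myc signal was higher than input at UBTF (ID 7343), a ribosomal RNA transcription factor, with 294 ± 12 against 21.9 ± 10.2 CPM and a log2 change of 3.73 ± 0.30 (adjusted p = 2.74e-18). DENR at 3.35 and CDK12 at 3.24 stood beside the proteasome gene PSMA7 at 3.22, the BMP receptor gene BMPR1A at 3.16, TFAP4 at 3.14 and ID4 at 3.12. BMP2 rose by 2.77 ± 0.25 (adjusted p = 2.17e-16). SLC14A2 at −2.03, CEP290 at −1.97, BCLAF1 at −1.92 and ANK3 at −1.88 were lower. Of the 871 TSSs with Myc signal over input in DAXX-only cells, 757 (86.9%) were also called higher here, against 227 for independent calls. edgeR quasi-likelihood called 8930 TSSs, 5776 higher and 3154 lower. Scaled to olfactory receptor TSSs, 7566 were higher and 345 lower, and the median of all TSSs moved from −0.12 to 0.29, so most lower calls depend on the scaling. Olfactory receptor genes, its reference, themselves had a median of −0.42, so this loss of lower calls follows from the choice of reference.

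Among lists tested for Myc over input in CBX2.1 cells, developmental transcription factors were higher at 86 and lower at 5 of 134 TSSs, or 88 and 5 adjusted over the list alone (adjusted p = 1.16e-12, and adjusted p = 0.13 with an estimated correlation). WNT, BMP and hedgehog ligands were higher at 21 and lower at 2 of 35, or 21 and 4 adjusted over the list alone (adjusted p = 6.16e-06, and adjusted p = 0.0844 with an estimated correlation). Called higher in the same way were Polycomb subunits (adjusted p = 0.000662, then 0.161), heat shock and stress genes (0.000477, then 0.155), canonical MYC targets (0.0075, then 0.161) and H3.3 chaperones and PML bodies (0.0373, then 0.26). Called lower were olfactory receptor genes (1.3e-06, then 0.26), germline genes (0.0125, then 0.18) and interferon-stimulated genes (0.0276, then 0.161).

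GAL4 signal over input in DAXX-only cells measured the background of the GAL4 antibody. It was higher at SLC39A10 (ID 57181), a zinc transporter gene, with 150 ± 49.4 against 28.4 ± 18.8 CPM and a log2 change of 2.42 ± 0.29 (adjusted p = 5.75e-09). STRBP stood at 2.18, EPC2 at 2.08, DAGLA at 2.05, NUDT3 at 1.93, HNRNPA2B1 at 1.79 and CBX3, which encodes a heterochromatin protein, at 1.72. edgeR quasi-likelihood called 17 TSSs, all higher, and DESeq2 called 26. BMP2 stood at 0.0665 (adjusted p = 0.976).

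In CBX2.1 cells GAL4 signal was higher than input at GNAO1 (ID 2775), a G protein subunit gene, with 209 ± 31.3 against 11.4 ± 4.02 CPM and a log2 change of 4.18 ± 0.33 (adjusted p = 6.94e-20). SOX21 at 4.15, IGF2 at 3.97, DPYSL4 at 3.92, NKX6-2 at 3.85 and the calcium channel gene CACNA1C at 3.78 were also higher. CEP290 at −2.33, INTS13 at −2.30, COP1 at −2.26 and HSPA8 at −2.24 were lower. WNT, BMP and hedgehog ligands were higher at 24 and lower at 5 of 35 TSSs, or 24 and 6 adjusted over the list alone, with a median of 1.81 (adjusted p = 4.13e-10, and adjusted p = 0.0324 with an estimated correlation). edgeR quasi-likelihood called 10049 TSSs, 6064 higher and 3985 lower, and under olfactory receptor scaling the median of all TSSs moved from −0.13 to −0.19.

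For GAL4 over input in CBX2.1 cells camera also called developmental transcription factors, with 99 higher and 3 lower of 134 TSSs, or 101 and 4 adjusted over the list alone (adjusted p = 5.2e-18, and adjusted p = 0.0942 with an estimated correlation). Polycomb subunits (0.0124, then 0.26) and heat shock and stress genes (0.02, then 0.26) were called higher. Ribosomal protein genes (0.0147, then 0.389), replication-dependent histone genes (0.0214, then 0.26) and germline genes (0.0143, then 0.176) were called lower. For GAL4 over input in CBX2.2 cells, ribosomal protein genes (0.0206, then 0.288), numbered ZNF genes (0.035, then 0.246) and replication-dependent histone genes (0.045, then 0.378) were called lower relative to other TSSs. Single TSSs called were 1 higher and 4 lower of 78 ribosomal, 34 higher and 16 lower of 506 ZNF, and 0 of 62 histone TSSs. Adjusted over each list alone they were 0 ribosomal, 27 higher and 6 lower ZNF, and 0 histone TSSs. fry did not call ribosomal protein genes in CBX2.1 cells (0.0536) or these 3 lists in CBX2.2 cells (0.112, 0.164 and 0.14). Nor did it call MYC targets in the inputs of CBX2.1 against DAXX-only cells (0.142) or developmental transcription factors for Myc over input in CBX2.2 cells (0.0506).

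In CBX2.2 cells GAL4 signal over input asked where CBX2.2 sat. It was higher than input at DPYSL4 (ID 10570), a dihydropyrimidinase-like gene, with 311 ± 65.4 (n = 3) against 15.2 ± 13.4 CPM (n = 2) and a log2 change of 4.35 ± 0.39 (adjusted p = 5.48e-17). The opioid receptor gene OPRK1 stood at 4.32, the RNA-binding protein gene CELF4 at 4.20, FGF14 at 4.10 and the Notch ligand gene DNER at 4.04. BMP2 rose by 3.10 ± 0.35 (adjusted p = 1.01e-12), BMP6 by 3.08, GBX1 by 2.99, SHH by 2.72, WNT9A by 2.63 and IRX4 by 2.59. WNT, BMP and hedgehog ligands were higher at 23 of 35 TSSs, or 23 higher and 1 lower adjusted over the list alone, with a median of 1.42 (adjusted p = 9.67e-16, and adjusted p = 0.161 with an estimated correlation). Developmental transcription factors were higher at 75 of 134, or 79 adjusted over the list alone, with a median of 1.09 (adjusted p = 3.42e-20, and adjusted p = 0.161 with an estimated correlation). The ubiquitin ligase gene NEDD4 at −1.92 ± 0.45 (adjusted p = 0.000405) was lower.

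edgeR quasi-likelihood called 3854 of 22140 TSSs, 3278 higher and 576 lower. Of the 3278, 3200 (97.6%) were also higher over input in CBX2.1 cells, against 898 for independent calls, and the changes correlated across TSSs with r = 0.809 and rho = 0.713. Without input replicate 2 of CBX2.2 cells 2361 TSSs were called, and the median of all TSSs moved from −0.042 to −0.10 under olfactory receptor scaling.

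Myc signal over input in CBX2.2 cells asked where DAXX-Myc sat beside CBX2.2. It was higher than input at DENR, with 508 ± 85 (n = 3) against 50.6 ± 4.92 CPM (n = 2) and a log2 change of 3.32 ± 0.36 (adjusted p = 3.45e-12), and at CDK12 at 3.26 ± 0.36 (adjusted p = 7.57e-12). ERCC6L2 at 3.01 and RPS19 at 2.45 were also higher. Ribosomal protein genes were higher at 27 of 78 TSSs, or 33 adjusted over the list alone, with a median of 0.58 (adjusted p = 6.99e-12, and adjusted p = 0.0942 with an estimated correlation). Of 35 WNT, BMP and hedgehog ligands 1 was called, also adjusted over the list alone, and the median was 0.27 (adjusted p = 0.261). BMP2 stood at 0.41 ± 0.34 (adjusted p = 0.434) and SHH at 0.82 ± 0.33 (adjusted p = 0.0777). Developmental transcription factors were higher at 27 of 134, or 28 adjusted over the list alone, with ZIC2 at 1.86 (adjusted p = 1.14e-05, and adjusted p = 0.291 with an estimated correlation). STAP1 at −2.13, TRIM33 at −1.93 and JCHAIN at −1.83 were lower.

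Other lists called for Myc over input in CBX2.2 cells were Polycomb subunits, with 7 higher and 2 lower of 28 TSSs, or 11 and 2 adjusted over the list alone (adjusted p = 0.00261, and adjusted p = 0.161 with an estimated correlation). Canonical MYC targets were higher at 10 of 47, or 11 higher and 1 lower adjusted over the list alone (adjusted p = 0.000218, and adjusted p = 0.161 with an estimated correlation). H3.3 chaperones and PML bodies (0.0146, then 0.182) and heat shock and stress genes (0.0048, then 0.161) were called higher. Olfactory receptor genes were lower at 62 of 329, or 85 adjusted over the list alone, with a median of −0.65 (adjusted p = 3.55e-17, and adjusted p = 0.153 with an estimated correlation), and germline genes had 2 higher and 2 lower of 40 (adjusted p = 0.0383, and adjusted p = 0.161 with an estimated correlation).

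edgeR quasi-likelihood called 3330 TSSs, 2085 higher and 1245 lower, and of the 871 TSSs higher in DAXX-only cells 653 (75%) were also higher here, against 82 for independent calls. Scaled to olfactory receptor TSSs, 8836 were higher and 74 lower, and the median of all TSSs moved from −0.021 to 0.62, so the lower calls depend on the scaling. Olfactory receptor genes, its reference, themselves had a median of −0.65, so this loss of lower calls follows from the choice of reference. The medians of imprinted, interferon-stimulated and germline genes turned from −0.22, −0.16 and −0.33 to 0.43, 0.47 and 0.32 under this scaling. It moved all TSSs nearly alike, so these turns do not set the lists apart from other TSSs. Of these lists, the germline list had been called lower. The count was 1680 and 683 without input replicate 1 and 2, and 2055 and 1873 without Myc replicate 1 and 2.

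Differences of the signals over input compared the isoforms. The Myc signal of CBX2.2 cells was lower than that of CBX2.1 cells at CPLX1 (ID 10815), a complexin gene, by a log2 difference of −3.28 ± 0.44 (adjusted p = 2.45e-07), at GNAO1 by −3.00 and at ATP6V1C2 by −2.84. BMP2 differed by −2.37 ± 0.38 (adjusted p = 5.06e-05), WNT9A by −2.01 ± 0.39 (adjusted p = 0.000604), EGR2 by −1.88 and IRX4 by −1.71. At BMP2 the Myc libraries of CBX2.2 cells held 73.0 ± 4.42 CPM against 55.1 ± 11.6 in input, and those of CBX2.1 cells 241 ± 18.9 against 35.2 ± 4.26. At CPLX1 input was 38.6 ± 14.9 CPM in CBX2.2 and 17.1 ± 2.87 CPM in CBX2.1 cells, which adds to its difference. Of 35 WNT, BMP and hedgehog ligands 9 were lower, or 19 adjusted over the list alone, and of 134 developmental transcription factors 19, or 30 adjusted over the list alone. These lists were not tested as lists across the tables. edgeR quasi-likelihood called 1019 of 22148 TSSs, 35 higher and 984 lower. The count was 242 under olfactory receptor scaling, where the median of all TSSs moved from −0.054 to 0.17, 275 and 596 without input replicate 1 and 2 of CBX2.2 cells, and 679 without Myc replicate 1 of CBX2.1 cells.

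GAL4 signal over input was also compared between the isoforms. It was lower in CBX2.2 cells at BARD1, a BRCA1 partner gene, by −2.67 ± 0.52 (adjusted p = 0.00375), at UBTF by −2.39 ± 0.45 (adjusted p = 0.00345), at the glucocorticoid receptor gene NR3C1 by −2.16 and at CERS2 by −2.11, and higher at DSPP by 2.78 ± 0.52 (adjusted p = 0.00345). At BARD1, UBTF and DSPP the input means lay in the opposite direction, which adds to these values. At BARD1 GAL4 signal was 34.2 ± 6.34 CPM in CBX2.2 and 70.4 ± 20.3 CPM in CBX2.1 cells, and input 28.3 ± 3.61 and 9.02 ± 1.58 CPM, while at DSPP input was 21.9 ± 4.54 and 48.7 ± 2.67 CPM and at UBTF 44.7 ± 22.9 and 22.0 ± 10.2 CPM. BMP2 stood at −0.63 ± 0.38 (adjusted p = 0.418) and SHH at −0.13 (adjusted p = 0.912). Of 35 WNT, BMP and hedgehog ligands 0 were called, also adjusted over the list alone. edgeR quasi-likelihood called 176 of 22148 TSSs, 17 higher and 159 lower, with 3425 at an unadjusted p under 0.05, close to the 3491 of the Myc difference. Each of the 5 calls named here was lost without input replicate 1 of CBX2.2 cells (adjusted p = 0.0598 for BARD1 and DSPP, 0.212 for UBTF, 0.119 for NR3C1 and 0.0849 for CERS2). The count rests on single libraries. It was 6 and 802 without GAL4 replicate 2 and 3 of CBX2.1 cells, 89, 80 and 84 without their input replicates, 115, 316 and 9 without GAL4 replicate 1, 2 and 3 of CBX2.2 cells, and 0 and 109 without input replicate 1 and 2 of CBX2.2 cells. It was 676 by DESeq2, 20 with only the compared groups in the fit and 21 under olfactory receptor scaling.

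Myc signal over input of CBX2.2 cells was compared with that of DAXX-only cells in the same way. BMP2 stood at 0.16 ± 0.40 and IRX4 at −0.15 ± 0.37, and among the smallest p-values were those of FOXF1 at 1.96, LRP10 at 1.76 and HORMAD1 at −1.87 (adjusted p = 0.997 for each). edgeR called 0 of 22148 TSSs, with 966 at an unadjusted p under 0.05, and DESeq2 called 0, with 937. In simulated counts, the like difference between CBX2.2 and CBX2.1 cells recovered 4.48% of changes of 2 times and 66.7% of 4 times. Gains of moderate size could thus be missed. Under olfactory receptor scaling the median of all TSSs moved from 0.014 to 0.25. In the top group of TSSs by GAL4 gain in CBX2.1 cells, the Myc signal over input of CBX2.2 cells lay 0.23 above that of DAXX-only cells, or 0.25 without correction for input (0.18 to 0.30 in single libraries), where GAL4 signal over input in CBX2.2 cells was 1.54.

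CBX2 and NCOA5 were followed because the first is on the plasmids and the other holds the reporter. The CBX2 TSS rose in the GAL4 libraries of CBX2.1 cells from 39.3 ± 4.77 to 148 ± 55.9 CPM, a log2 change of 1.90 ± 0.26 (adjusted p = 1.48e-09), and in the Myc libraries by 1.10 ± 0.25 (adjusted p = 0.000375). As a difference over input the Myc change was the same size, 1.10, and was not called. In input it stood at 0.0044 ± 0.30 (adjusted p = 1). For GAL4 over input in CBX2.2 cells the CBX2 TSS stood at 1.39 (edgeR adjusted p = 0.000147). The NCOA5 TSS fell in the GAL4 libraries of CBX2.1 cells from 49.4 ± 7.32 to 24.6 ± 1.89 CPM, a log2 change of −0.996 ± 0.303 (adjusted p = 0.0052), and stood at −0.28 ± 0.30 in the Myc libraries (adjusted p = 0.579). Over input, NCOA5 was called lower for Myc in CBX2.1 cells, at −1.02 (edgeR adjusted p = 0.00303). Most lower calls of that comparison depended on the scaling. NCOA5 was not called for Myc in DAXX-only cells, at −0.509, or CBX2.2 cells, at −0.627, nor for GAL4 in CBX2.2 cells, at −0.295. ATRX, whose protein partners DAXX in H3.3 deposition, stood at 0.17 (adjusted p = 0.686) for GAL4 and −0.17 (adjusted p = 0.765) for Myc. The reporter's own sequence has no window in the counts.

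**Figure D3:**
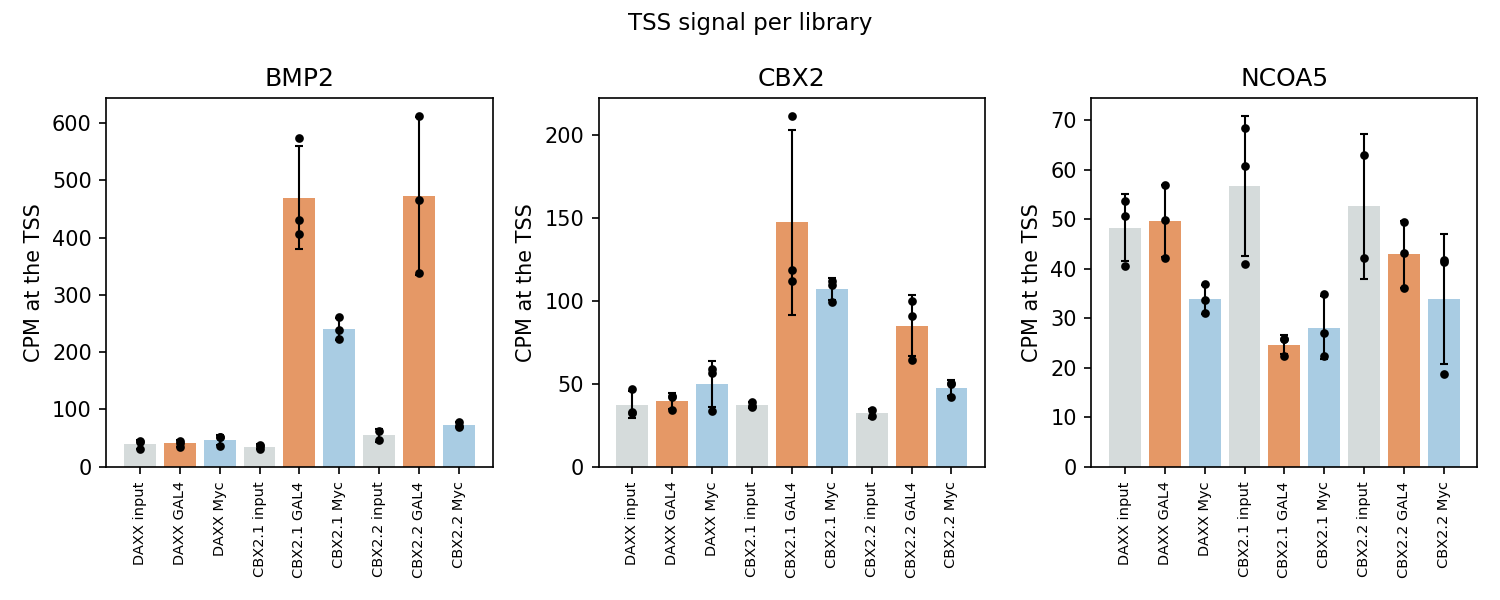
CPM at the TSSs of BMP2, CBX2 and NCOA5 in each library (points), with the group mean (bar from 0) and SD (error bar), for input (grey), GAL4 (orange) and Myc (blue) of DAXX-only, CBX2.1 and CBX2.2 cells, scaled over all libraries together. BMP2 carried GAL4 signal of 470 CPM in CBX2.1 and 473 CPM in CBX2.2 cells, and Myc signal of 241 and 73.0 CPM.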

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

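The test of recognition of GAL4DBD by the Myc antibody and the test of scaling were chosen after the results were seen.

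Effects over input differed between kinds of cell in tests of the difference itself. For GAL4 signal over input, 176 TSSs differed between CBX2.2 and CBX2.1 cells, and 5853 between CBX2.1 and DAXX-only cells. For Myc signal over input, 1019 TSSs, BMP2 and WNT9A among them, differed between CBX2.2 and CBX2.1 cells, and 2152 between CBX2.1 and DAXX-only cells. Without input replicate 1 of CBX2.2 cells the 176 became 0 and the 1019 became 275. The other libraries that moved the 176 were GAL4 replicates 2 and 3 of CBX2.1 cells (6 and 802), their inputs (89, 80 and 84), GAL4 replicates 1, 2 and 3 of CBX2.2 cells (115, 316 and 9) and input replicate 2 of CBX2.2 cells (109), and those that moved the 1019 were input replicate 2 of CBX2.2 cells (596) and Myc replicate 1 of CBX2.1 cells (679).

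Myc signal was higher in CBX2.1 cells at TSSs with more GAL4DBD-CBX2.1, such as BMP2 and SHH. A higher yield of the Myc immunoprecipitation would scale Myc signal already there. Among TSSs below the median of Myc signal over input in CBX2.2 cells, however, the median Myc change was 0.63 at 880 TSSs with more GAL4 signal. It was −0.21 at 10194 others, and the difference formed within each library had a median of 0.825 (0.762 to 0.836). The test covers only these 880 of the 6020 TSSs with more GAL4 signal. From the bottom to the top group by GAL4 change, Myc signal over input also rose without CBX2.1. It went from −0.24 to 0.42 in DAXX-only cells and from −0.37 to 0.64 in CBX2.2 cells. A yield could thus add to the gain at the other TSSs, where this test cannot decide. Recognition of GAL4DBD by the Myc antibody would give like Myc gains with both fusions. At 3200 TSSs with both, the Myc gain per GAL4 gain was 0.636 in CBX2.1 and 0.218 in CBX2.2 cells. This was a ratio of 0.343 (0.256 to 0.379 in single libraries). A batch of the immunoprecipitation in CBX2.2 cells could also lower the ratio, so it cannot decide on recognition. Were the Myc libraries of CBX2.1 cells GAL4 libraries under a wrong name, they would lack signal at the 258 TSSs called for Myc in DAXX-only and CBX2.2 cells but not for GAL4, yet they stood 0.874 above the GAL4 libraries there, which were low in part because the TSSs were chosen without GAL4 calls. A candidate explanation is that DAXX-Myc sits where CBX2.1 sits, as a hypothesis from the same data. Binding of the Myc antibody to GAL4DBD or to untagged MYC stays open, as Myc chromatin without DAXX-Myc was not analysed here.

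CBX2.2 cells had GAL4 signal at the TSSs of BMP2, SHH and GBX1 with less Myc gain than CBX2.1 cells. Lower GAL4 signal would leave like Myc gains at like GAL4 signal. TSSs with GAL4 signal over input of 1 to 2 log2 units were 1999 in CBX2.2 and 3115 in CBX2.1 cells, chosen separately. Their Myc gain over DAXX-only cells was 0.289 in CBX2.2 and 0.864 in CBX2.1 cells, a share of 0.334 (0.243 to 0.363 in single libraries). GAL4 signal also depends on the yield of each GAL4 immunoprecipitation. This test therefore cannot exclude that less fusion sat at these TSSs in CBX2.2 cells. A lower yield of the Myc immunoprecipitation would lower Myc signal at 343 TSSs called for Myc in DAXX-only cells but not for GAL4. There CBX2.2 cells stood 0.348 above CBX2.1 cells, with libraries at 1.07 to 1.26 against 0.609 to 1.16. DAXX-only cells, in which these TSSs were chosen, stood at 1.15, CBX2.2 cells at 1.1 and CBX2.1 cells at 0.753. Scaling to all TSSs while many gained Myc signal could lower the value of CBX2.1 cells, so this test cannot decide. Between the inputs of CBX2.2 and CBX2.1 cells edgeR called 0 TSSs, with 799 at an unadjusted p under 0.05, but a batch of the immunoprecipitation cannot be told apart from the kind of cell, which keeps it open. A difference between the isoforms in how they meet DAXX stays an open explanation, and the amounts of DAXX-Myc and of the fusions in the cells were not analysed here.

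GAL4 signal was lower at 3371 TSSs in CBX2.1 cells, HSPA8 and ZNF569 among them. Scaling to all TSSs while 6020 gained could push others down, which would leave few lower TSSs when libraries are scaled to olfactory receptor genes, but 4912 were then lower. That count was 1899 without GAL4 replicate 2 of CBX2.1 cells and 6698 without replicate 3, and 3540 to 4205 without each of the other 4 libraries of the comparison. Olfactory receptor genes, the reference, themselves had a median of 0.21 in this comparison, so scaling to them moves other TSSs down. With such a reference and so wide a range, this test leaves open whether scaling could account for the lower TSSs. No biological explanation was tested for the lower TSSs.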

How the results depend on the processing

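No alternative in this part was chosen after the results were seen. Counts not given here stayed within 1.5 times the main count, and no called gene, and no called list by camera, reversed. camera compares a list with other TSSs, and germline genes stayed called lower for Myc against input in CBX2.2 cells under olfactory receptor scaling, although their median turned from −0.33 to 0.32. Under olfactory receptor scaling, Myc against input called 4117 TSSs in DAXX-only and 8910 in CBX2.2 cells, and the isoforms differed at 21 TSSs for GAL4 and 242 for Myc. camera with an estimated correlation called 3 lists, the WNT, BMP and hedgehog ligands each time. With only the compared groups fitted, the isoforms differed at 20 TSSs for GAL4. DESeq2 called 26 TSSs for GAL4 against input in DAXX-only cells and 676 for GAL4 between isoforms. As differences over input, CBX2.1 and DAXX-only cells differed at 5853 TSSs for GAL4, of which 5629 were also called without input, and 2152 for Myc, of which 2065 were. Above the median count, GAL4 and Myc changes correlated at 0.881. The cause was not tested.

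Leaving out each library in turn gave 407 (without Myc replicate 2) to 1271 TSSs for Myc against input in DAXX-only cells, with 578, 609 and 501 without input replicates 1 to 3 and 478 without Myc replicate 1. It gave 2361 (without input replicate 2) to 4420 for GAL4 against input in CBX2.2 cells. It gave 683 (without input replicate 2) to 3311 for Myc there, with 1680 without input replicate 1, and 2055 and 1873 without Myc replicates 1 and 2. Between isoforms it gave 0 to 802 for GAL4 and 275 to 853 for Myc, with single libraries listed above. The correlation of GAL4 and Myc changes was 0.791 to 0.827. GAL4 and Myc of CBX2.1 against DAXX-only cells gave 7009 to 10733 and 3350 to 3887 TSSs. Against input it gave 7230 to 8105 for Myc and 8083 to 11155 for GAL4 in CBX2.1 cells and 13 to 15 for GAL4 in DAXX-only cells, and 0 for input and for Myc of CBX2.2 against DAXX-only cells. In CBX2.2 fits without 1 input, the lone input is assumed to vary like the other groups. The self-test recovered few changes of 1.5 times.

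Residuals of same-numbered libraries after the group fit correlated at −0.111 to 0.229, with 5 of 53 above 0.1, and others at −0.24 to 0.127, with 3 of 106. For Myc against input in DAXX-only cells alone, all same-numbered values (0.0451 to 0.107) lay above all others (−0.0687 to 0.00385), so pairing stays open. With a replicate block, the counts were 9335 and 4318 TSSs for GAL4 and Myc of CBX2.1 against DAXX-only cells, 1000 for Myc against input in DAXX-only cells, and 913 for Myc between isoforms.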

Other observations

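The tests of other splits of the libraries were planned; the overlaps below are described without a test.

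Myc signal of DAXX-only cells, which hold no CBX2 fusion, lay in part at TSSs that carried GAL4DBD-CBX2.1. Of the 871 TSSs with Myc signal over input in DAXX-only cells, 527 (60.5%) had GAL4 signal over input in CBX2.1 cells, against 239 for independent calls, and ZIC2 and H3-3A, which stood at 1.49 and 1.02 for Myc, stood at 2.81 and 2.23 for GAL4 there. The H3-3A Myc call is lost without input replicate 3 or Myc replicate 1 of DAXX-only cells. Across TSSs the signals correlated with r = 0.489 and rho = 0.506.

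GAL4 signal over input in CBX2.2 cells overlapped with the Myc gain of CBX2.1 cells, with which it shares no library. Of the 3278 TSSs with GAL4 signal in CBX2.2 cells, 2726 (83.2%) gained Myc signal in CBX2.1 cells, against 581 for independent calls, and 1 lost it, against 56. IGF2, IRF1 and EGR2 stood at 2.94, 2.11 and 2.39 for GAL4 in CBX2.2 cells and rose by 1.92, 1.66 and 1.31 for Myc in CBX2.1 cells. Across TSSs the changes correlated with r = 0.739 and rho = 0.621.

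The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. The real counts, with the highest of the other splits, were 9391 and 0 for GAL4 and 4300 and 0 for Myc of CBX2.1 against DAXX-only cells, and 0 and 0 for input. Against input they were 1027 and 0 for Myc and 17 and 1 for GAL4 in DAXX-only cells, and 8930 and 0 for Myc and 10049 and 0 for GAL4 in CBX2.1 cells. The correlation of GAL4 and Myc changes was 0.832, against 0.564 as the highest of the other splits of the Myc libraries. Every other split mixes libraries of both groups, which keeps part of the difference and widens the spread within groups. These splits therefore do not measure chance.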
